A study of Homo sapiens with 16 samples.

How the data were processed

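A549 cells, an established human lung adenocarcinoma line, were exposed to carbon ions (C12) or to X-rays and sampled 1h or 4h later. Per the labels, 16 independent cultures were each divided into an irradiated and a control plate, and the RNA of both plates was hybridised together on 1 Agilent array with 2 dyes, Cy3 and Cy5. Each of the 4 combinations of radiation quality and time had 4 arrays, and the labels describe a balanced dye swap. The labels also state that RNA of 2 independent experiments was pooled before labelling. No radiation dose was given for these samples in the sources used here, so the C12 and X-ray exposures cannot be set against each other at equal dose.

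The values used were log2 ratios of the 2 dyes as the authors deposited them, 1 value per feature and array, for 45220 features with 0 missing values. The submitters' processing notes name limma without a version. Background correction, normalization within arrays, the log base and the direction of the ratios are not given in the sources used here. Base 2 was taken from limma's usual output. The deposited values ran from -3.384 to 2.932, and the SD over features was between 0.4142 and 0.4143 on every array, so the 16 arrays had been brought to almost the same distribution. The median of the deposited values lay between -0.04151 and -0.03915 on every array. No signals or background values were used here, so the number of arrays limits the precision.

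The direction of the ratios was not settled by the labels and was chosen after the values had been seen. Readings fixed before the data were examined were Cy5 over Cy3 (turned by the labelled dye of the irradiated plate), its inverse, and irradiated over control as deposited. A p53 target list had been named in advance as the positive control for this choice, and none of these readings gave it a positive mean in both X-ray groups. A total of 4 sign patterns over replicates 1 to 4 was then examined: as deposited, the dye code of the C12 arrays, the dye code of the X-ray arrays, and the product of both codes. C12 arrays with the same labelled dye orientation correlated over features with r from -0.869 to 0.853 (median -0.831). Those with the opposite orientation ran from -0.85 to 0.846 (median -0.000514), so the labelled dye did not set the sign. C12 arrays that share the dye code of the X-ray array of the same number and time correlated with a median r of 0.839 (0.801 to 0.853). With the opposite code the median was -0.834 (-0.869 to -0.802). For X-ray arrays the pattern was weak. Those sharing the dye code of the C12 array had a median r of 0.142 (-0.123 to 0.415). Those with the opposite code had a median r of -0.2 (-0.531 to 0.618). Among features without a gene name, the strongest pattern was the dye code of the other radiation quality in all 4 groups. The likely reading is therefore that ratios of Cy5 over Cy3 had been multiplied with the dye code of the other quality. Each ratio was multiplied by that code and by the labelled dye code of its own irradiated plate, which gives irradiated over control under this reading. The result is a rule from labels with no choice left for single arrays, but the overall sign rests on the p53 list, and its mean in the X-ray groups entered the choice, so that its direction is not evidence and its p-values there come after a selection. If the ratios run the other way, each rise given here is a fall and each fall a rise, with the same sizes and tests. The product of both codes also equals replicates 1 and 2 against replicates 3 and 4, so an additive difference between those replicates would look like a response.

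Features were named through a table of the platform's annotation. A single gene symbol was given for 31332 features, several for 93, and 13795 were unnamed here. Symbols were updated through Entrez identifiers for 31291 features, and the file's symbol was kept for 41. Ratios of all features with the same symbol were averaged, which gave 18334 genes, of which 7759 had more than 1 feature and the largest number was 16. Features with several symbols were left out of all tests, and unnamed features were used for the choice of direction and tested separately, where those that passed were only counted.

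Testing used limma 3.58.1 and statmod 1.5.0 in R 4.3.3. A linear model with 4 group means and 1 dye coefficient per gene was fitted to all 16 arrays, followed by empirical Bayes moderation (11 residual degrees of freedom, 6.582 prior degrees of freedom). The 8 comparisons were each group against 0, C12 minus X-ray at each time, and 4h minus 1h for each quality. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors of fold changes are standard errors from this model with n = 4 arrays per group. Because the spread of a gene was shared by all 16 arrays, its standard error was the same in each group. Fixed before the data were examined were 20 gene lists with 636 genes, of which 588 were measured. These held p53 targets, mitotic G2/M, G1/S and replication, replication-dependent histone, immediate early, NF-kB, interferon-stimulated, HIF-1 and hypoxia, ATF4 and unfolded protein response, heat shock, NRF2, double-strand break repair, TGF-beta, cholesterol synthesis, ribosomal protein, ribosome biogenesis and MYC, and housekeeping genes, and markers of alveolar epithelium and adenocarcinoma, leukocytes, and fibroblasts and endothelium. Each list was tested with limma's fry, which asks whether its genes move on balance in 1 direction and does not compare them with other genes, with adjustment over the 20 lists, and with camera, which compares them with other genes, at a preset correlation of 0.01 and at an estimated correlation. The genes named are, per comparison, up to 10 of the largest rises and 10 of the largest falls among called genes with the same direction on all 4 arrays, the 5 smallest p-values where fewer than 5 genes passed, up to 4 members per list, and a short set of radiation, cell cycle and hypoxia genes. Further members of lists and of alternative fits were named after their values were seen, among them XPC, DDB2, TNFRSF10B, PPM1D and POLH for X-ray 4h and TP53INP1 for X-ray 1h.

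The procedure was tested on simulated ratios with the arrays' own scatter and dye effects, over 18334 genes with 200 changed genes. For C12 4h, 44.8% of the genes changed by 0.5 on the log2 scale were recovered and 98.5% of those changed by 1. For X-ray 4h, the shares were 38.8% and 95.5%, with 10 unchanged genes among 166 calls. The simulated errors were independent between genes, and 200 changed genes ease the adjusted threshold. In the real data 2 genes passed for C12 4h, and GDF15 with a log2 change of 1.02 did not. The shares recovered are therefore not the power of the real comparisons. Alternatives covered the dye term, centring and scaling of arrays, tests per feature, robust moderation, array weights, fits on the compared groups alone, the replicate number as a block, a fold change threshold, leaving out each array, other directions, and other set tests. Replicate numbers are not described as shared batches in the labels, and the design used no block; the residuals of arrays of the same number did not correlate best with each other after removal of 1 dye coefficient per quality. How the authors scaled and centred the ratios and which direction they run stay unknown.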

Results

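Gene expression in A549 lung adenocarcinoma cells was measured on 16 arrays, each comparing an irradiated plate with the control plate of the same culture. Cells were sampled 1h and 4h after carbon ions (C12), a densely ionising particle beam, or after X-rays, with 4 arrays per group. The arrays covered 18334 named genes. All directions below are likely ones: the labels alone did not settle the sign of the deposited ratios, the sign rule was chosen after the values had been seen, and the inverse sign would exchange every rise and fall. The list of p53 targets was the positive control for that choice, and its mean in the X-ray groups entered it, so its direction is not a finding and its p-values in these groups come after a selection. The dose was not given in the sources used here, so differences between C12 and X-rays describe these exposures and not the qualities at equal dose.

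**Figure D1:**
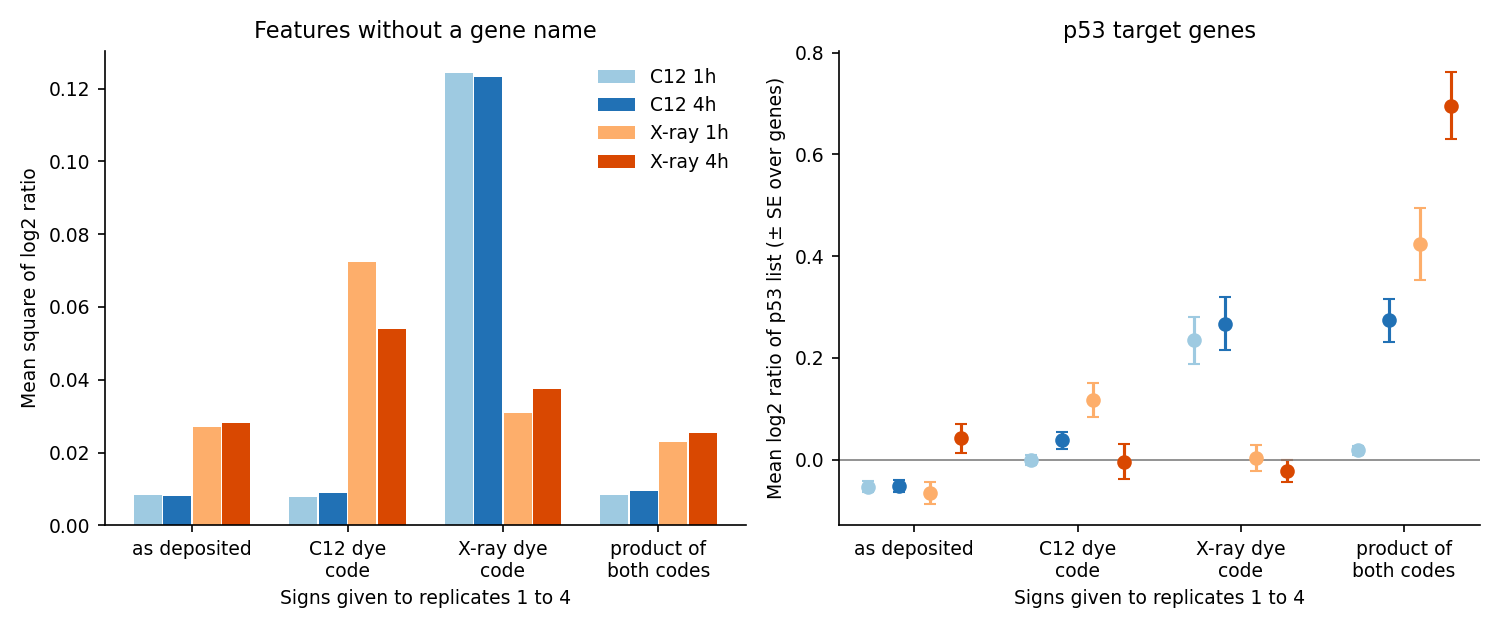
Left, mean square of the log2 ratio of features without a gene name, by the signs given to replicates 1 to 4 (as deposited, dye code of the C12 arrays, dye code of the X-ray arrays, product of both), for the 4 groups of 4 arrays. Right, mean log2 ratio of the 45 measured p53 targets under the same signs (bars, SE over genes); C12 4h, X-ray 1h and X-ray 4h lie at 0.27, 0.42 and 0.70 under the product, and C12 4h also at 0.27 under the X-ray dye code.

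At 4h after X-rays, the genes with the highest rises included GDF15, a stress-induced cytokine (Entrez gene 9518), which rose by 1.74 ± 0.23 on the log2 scale (SE, n = 4), TP53INP1 (Entrez gene 94241), which rose by 1.66 ± 0.20, and CDKN1A, the cyclin-dependent kinase inhibitor of the G1 checkpoint (Entrez gene 1026), which rose 2.73-fold (log2 1.45 ± 0.14, limma adjusted p = 8.19e-05). The ceramidase gene ACER2 rose by 1.41 ± 0.14 and the polo-like kinase gene PLK3 by 1.29 ± 0.20. Of the 46 mitotic genes measured, 7 fell, a list result that depended on single arrays and was lost in camera (adjusted p = 0.076 with an estimated correlation). Among the 7, CKS2, a subunit of cyclin-dependent kinases (Entrez gene 1164), fell by 1.15 ± 0.20 on the log2 scale (adjusted p = 0.0107), the cyclin B gene CCNB1 fell by 0.83 ± 0.14 and the mitotic kinase gene PLK1 fell by 0.86 ± 0.15. The largest rises and falls were chosen among genes with the same direction on 4 of 4 arrays, so that agreement is not further support for them. CKS2 did not pass without replicate 1 (adjusted p = 0.0967), 3 (0.116) or 4 (0.067), nor did CCNB1 (0.0676, 0.0562 and 0.066), and PLK1 did not pass without replicate 3 (0.0849) or 4 (0.0815), nor PLK3 without replicate 3 (0.077).

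In total 96 genes rose and 8 fell 4h after X-rays, out of 18334 tested. Of the 45 measured p53 targets, 23 rose, 0 fell and 22 did not pass, and 34 rose when adjusted over the list alone (fry adjusted p = 1.35e-05, 44 of 45 positive). The members that rose included the damage recognition genes XPC (1.03) and DDB2 (0.94), the death receptor genes FAS (0.87) and TNFRSF10B (0.89), the phosphatase gene PPM1D (1.07) and the translesion polymerase gene POLH (0.65), as log2 changes; apart from FAS, these were chosen for naming after their values were seen. MDM2, which encodes the ubiquitin ligase of p53, had a change of 0.43 ± 0.13 and did not pass (adjusted p = 0.246). Another 71 of the genes that rose were in none of the 20 lists, among them PHLDB3 (1.26), VWCE (1.25), THSD1 (1.17) and the epithelial transcription factor gene GRHL3 (1.09). ACTA2, which encodes smooth muscle actin, rose by 0.79 ± 0.12 and was the only member of the 20 fibroblast and endothelial markers measured to pass, and the chaperone gene HSPA4L (0.65 ± 0.11) was the only one of 20 heat shock genes. Without replicate 3, PHLDB3 (adjusted p = 0.0519), THSD1 (0.151), ACTA2 (0.0604) and HSPA4L (0.077) did not pass.

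Of the 46 measured mitotic G2/M genes, 7 fell 4h after X-rays, 0 rose and 39 did not pass, and all 46 had negative estimates (mean -0.58, fry adjusted p = 0.0383). Adjusted over the list alone, 33 fell and 0 rose. This call was lost by camera (adjusted p = 0.076 with an estimated correlation), without the dye term (adjusted p = 0.122), in a fit on the X-ray 4h arrays alone (0.997) and on leaving out replicate 1 (0.215), replicate 3 (0.206) or replicate 4 (0.315). The 7 were CKS2, PSRC1, PLK1, CCNB1, CCNA2, AURKA and CDC25C, and the long noncoding RNA SNHG7 was the other gene that fell (-0.73 ± 0.13). Without replicate 3, 15 genes rose and 0 fell. AURKA and CDC25C also did not pass without replicate 1 (limma adjusted p = 0.191 and 0.113) or 4 (0.218 and 0.145). SNHG7 did not pass without replicate 1 (0.0563) either. CDC20 had a change of -0.74 ± 0.17 (adjusted p = 0.0522) and KIF20A of -0.63 ± 0.19 (adjusted p = 0.253). The mean of the list was between -1.07 and -0.71 on 3 of the X-ray 4h arrays and 0.20 on replicate 2. On replicate 2 housekeeping genes had a mean of 0.66. The count of changed genes and its balance depended strongly on single arrays. Without replicate 2, 1322 genes passed, with 187 up and 1135 down, against 15 without replicate 3 and 61 without replicate 1. Array weights gave replicate 2 a weight of 0.0837 and left 2 genes.

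**Figure D2:**
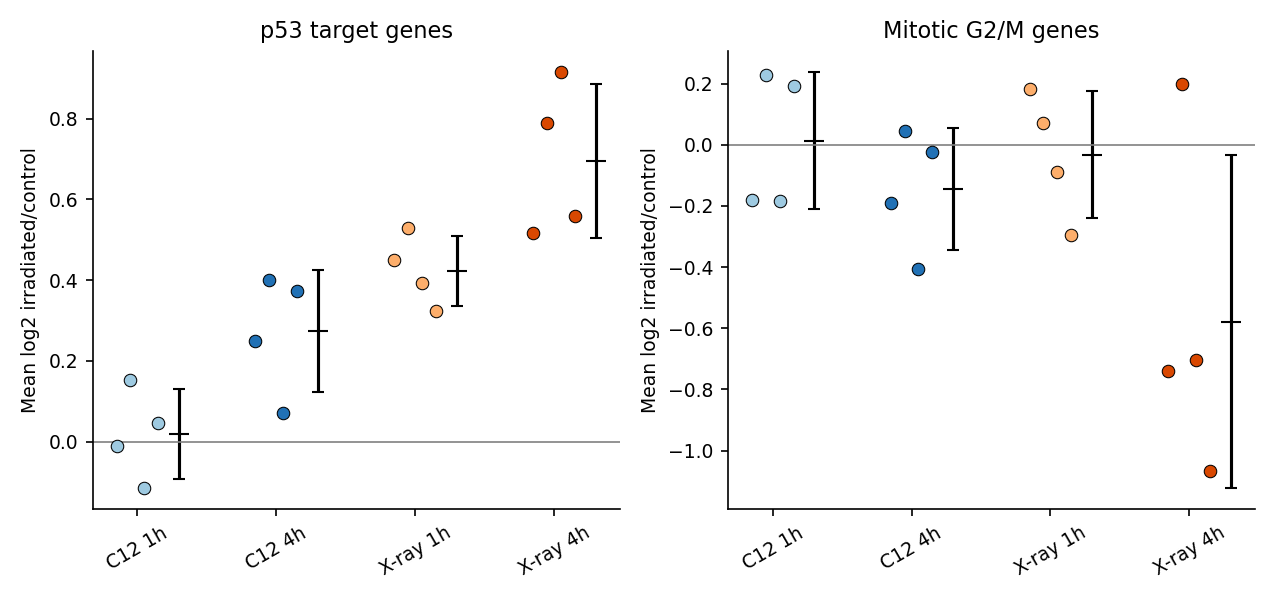
Mean log2 ratio of irradiated over control of the p53 targets (left) and the mitotic G2/M genes (right) on each array after removal of the dye coefficient; points are the 4 arrays of a group, and lines with bars their mean and SD. All 4 arrays of both X-ray groups and of C12 4h have a positive p53 mean, and X-ray 4h replicate 2 stands at 0.20 in the mitotic list while the others are at -0.71 or lower.

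At 1h after X-rays, 8 genes rose and 1 fell. The 8 were GDF15 (1.76 ± 0.23), PLK3 (1.59 ± 0.20), the growth arrest gene GADD45A (1.53 ± 0.24), PPM1D (1.32 ± 0.16), CDKN1A (1.03 ± 0.14), SERTAD1 (0.94 ± 0.14), the pro-apoptotic gene BBC3 (0.88 ± 0.12) and SESN2 (0.85 ± 0.12), all members of the p53 list, with limma adjusted p between 0.0026 and 0.00998. SNHG7 fell by 0.80 ± 0.13 (adjusted p = 0.0175), and did not pass without replicate 1 (0.411), 3 (0.0577) or 4 (0.355). In the p53 list 8 rose, 0 fell and 37 did not pass, and 16 rose when adjusted over the list alone (fry adjusted p = 0.00348, mean 0.42). TP53INP1, at 0.77 ± 0.20 with an adjusted p of 0.91, did not pass at this time. Mitotic genes had a mean of -0.03 (adjusted p = 0.949). A fit on the X-ray 1h arrays alone called 1 gene, and its adjusted p for the p53 list was 0.186. Without the dye term 0 genes passed, and 5, 4 and 3 passed without replicate 1, 2 and 3, with PPM1D and PLK3 among them each time.

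At 4h after C12, 2 genes rose and 0 fell. CDKN1A rose 2.18-fold (log2 1.12 ± 0.14, limma adjusted p = 0.00769) and BBC3 rose 1.72-fold (0.78 ± 0.12, adjusted p = 0.0324), each on 4 of 4 arrays. Of the 3 features of BBC3, 2 had the direction of the gene, here and at X-ray 1h, against 11 of 11 for CDKN1A. GDF15 at 1.02 ± 0.23, PLK3 at 0.78 ± 0.20 and GRHL3 at 0.46 ± 0.11 had the next smallest p-values and did not pass, and GDF15 stood at 0.68 without replicate 3 and PLK3 at 0.45 without replicate 4. The p53 list had 40 of 45 positive estimates and a mean of 0.27, with an fry adjusted p of 0.0796, above the threshold, and 8 members rose when adjusted over the list alone. The camera test gave an adjusted p = 0.000599 with an estimated correlation, and fry passed the list without replicate 3 (adjusted p = 0.0207). Mitotic genes had negative estimates in 46 of 46 cases with a mean of -0.14 (fry adjusted p = 0.999). Fitted on the C12 4h arrays alone, whose scatter was smaller, 18 genes rose and 8 fell, among them GDF15, GADD45A (0.92 ± 0.09), PPM1D (0.61 ± 0.07) and PLK3, and the centromere gene CENPA (-0.56 ± 0.09). Leaving out replicate 1, 2 or 4 left 0 called genes, leaving out replicate 3 left CDKN1A alone (adjusted p = 0.018), and no gene passed without the dye term.

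**Figure D3:**
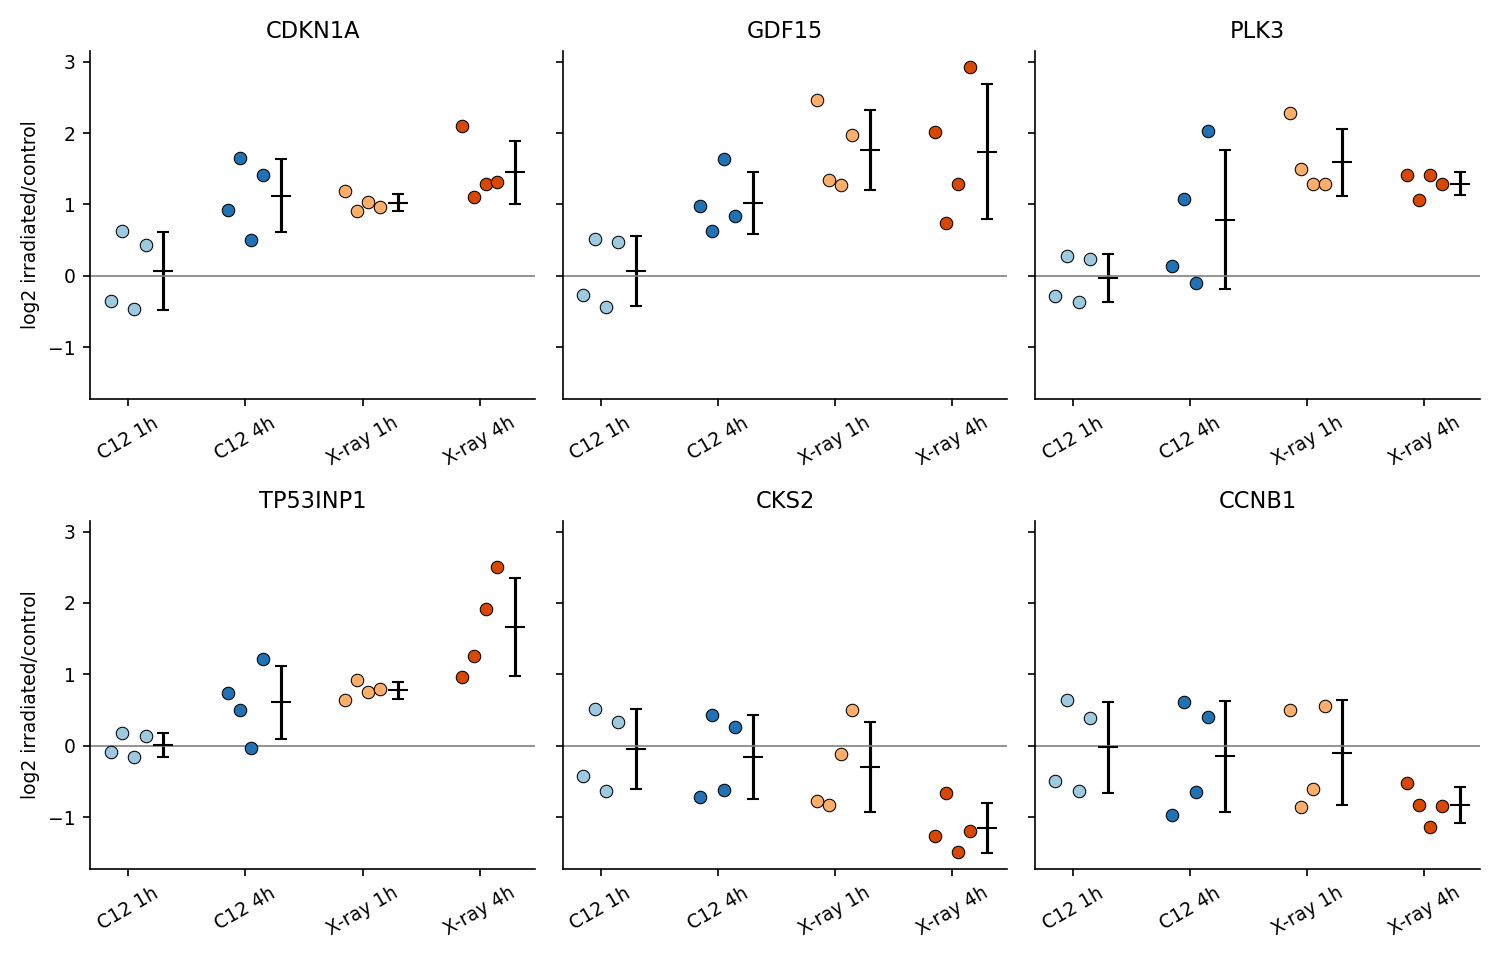
Log2 ratio of irradiated over control of 6 genes on each of the 16 arrays; points are arrays, and lines with bars the mean and SD of the 4 arrays of a group. CDKN1A is above 0 on all arrays except 2 of C12 1h, and CKS2 and CCNB1 are below 0 on all 4 X-ray 4h arrays.

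At 1h after C12, 0 genes passed by limma, and 29 of 18334 had an unadjusted p under 0.05. That share, and that of 44 genes at C12 4h, is far below the 0.05 that unchanged genes would give on average. The model used 1 spread per gene for all arrays, while the residual SD averaged 0.114 on C12 arrays and 0.283 on X-ray arrays. Standard errors were therefore likely too large for C12. For X-rays the shared spread would make them too small, but the values did not settle this. At X-ray 1h, 472 genes had an unadjusted p under 0.05, also below that share, and at X-ray 4h 1232 did, above it. With 1 dye coefficient per quality, 16 genes passed for X-ray 1h against 9, and 221 for X-ray 4h against 104. The shared dye coefficient had thus added to the X-ray errors. Counts of called genes cannot be compared between the qualities on that account. No alternative that kept the direction of the ratios called a gene in this group. CDKN1A had a change of 0.06 ± 0.14, GDF15 of 0.07 ± 0.23 and PPM1D of -0.01 ± 0.16. The p53 list had a mean of 0.02 over 45 genes (fry adjusted p = 0.986), with 2 of 4 arrays positive. None of the other lists passed in this group, where the adjusted p was 0.986 for every list.

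The direct comparison of C12 with X-rays asked whether the responses to these exposures differed. No single gene passed by limma at either time, with 146 genes at an unadjusted p under 0.05 at 1h and 329 at 4h. The smallest p-values at 1h belonged to PPM1D (-1.33 ± 0.22, adjusted p = 0.178), PLK3 (-1.62 ± 0.28, adjusted p = 0.178) and GDF15 (-1.69 ± 0.33, adjusted p = 0.432), each lower after C12. With only the 8 arrays of this comparison in the fit, GDF15 (adjusted p = 0.00695) and PPM1D (adjusted p = 0.0194) passed. At 4h the smallest p-values belonged to the calcium channel gene ORAI3 (-0.73 ± 0.14), SMIM10L2B (-0.89 ± 0.18) and INPP5D (-0.75 ± 0.15), each with an adjusted p of 0.534. As a list, the p53 targets were lower after C12 than after X-rays at 4h by a mean of 0.42, that is -0.42 for C12 minus X-ray, with 43 of 45 members negative and 0 passing singly, or 12 when adjusted over the list alone (fry adjusted p = 0.0232). The difference at 1h was -0.41 (fry adjusted p = 0.0716, camera adjusted p = 0.012 with an estimated correlation). At both times the X-ray means of this list had entered the choice of direction, so these p-values come after a selection. The call at 4h was lost in a fit on these 8 arrays alone (adjusted p = 0.343) and without the dye term (0.155), and on leaving out C12 4h replicate 1 (0.0644), C12 4h replicate 3 (0.089) or X-ray 4h replicate 3 (0.0816). Mitotic genes were at 0.43 for C12 minus X-ray at 4h, with 46 of 46 positive, and did not pass (fry adjusted p = 0.728), but passed without X-ray 4h replicate 2 (adjusted p = 0.0103).

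**Figure D4:**
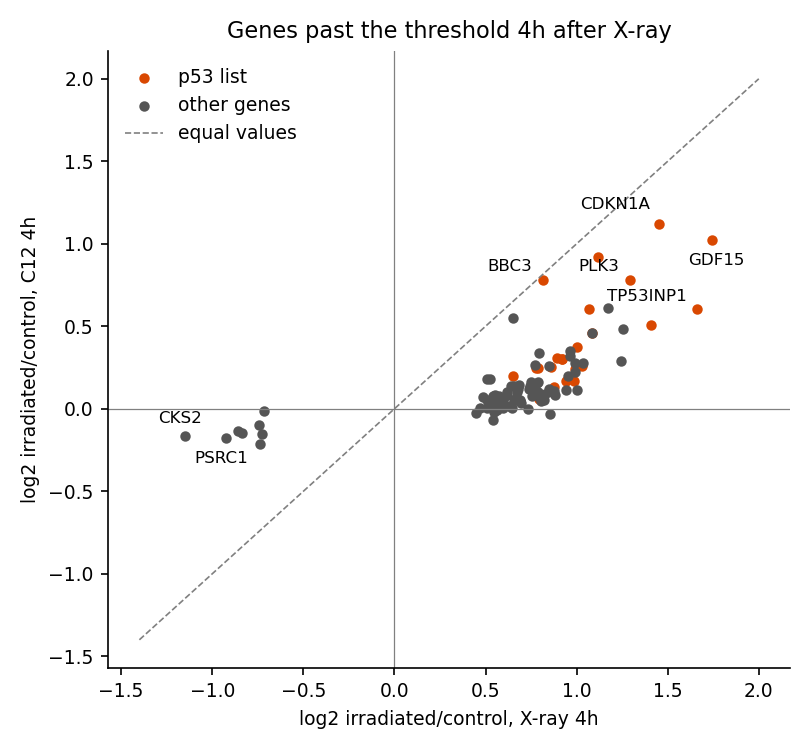
Log2 ratio of irradiated over control 4h after X-rays (horizontal) against 4h after C12 (vertical) for the 104 genes that passed 4h after X-rays; coloured points are p53 list members and the dashed line marks equal values. Of the 96 genes that rose after X-rays, 91 are above 0 after C12, with a median of 0.12 against 0.78 after X-rays.

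The groups were also compared gene by gene. Of the 96 genes that rose 4h after X-rays, 91 were positive 4h after C12 (53.5% of all genes were), with a median of 0.12, 88 were positive 1h after X-rays (median 0.19) and 70 were positive 1h after C12 (median 0.02). The median of the same genes 4h after X-rays, where they were selected, was 0.78. All 8 genes that fell 4h after X-rays were negative 4h after C12 (median -0.15). Across genes, fold changes of C12 4h and X-ray 4h correlated with r = 0.29, those of C12 1h and X-ray 1h with 0.01, and those of C12 4h and X-ray 1h with 0.05. With both times of a quality the values were 0.16 for C12 and 0.15 for X-rays, and C12 1h, with 0 genes called by limma and 29 at an unadjusted p under 0.05, correlated with X-ray 4h at 0.12. Genes are not independent replicates, and no control plates were shared between groups. The 2 genes called after C12 4h and all 8 that rose 1h after X-rays were also among those that rose 4h after X-rays, against 0.0105 and 0.0419 for independent lists.

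Between 1h and 4h, 0 genes passed by limma for either quality, with 24 genes at an unadjusted p under 0.05 after C12 and 645 after X-rays. After C12 the smallest p-values were those of CDKN1A (1.06 ± 0.20 for 4h minus 1h) and BBC3 (0.67 ± 0.17), which passed when only the C12 arrays were fitted (adjusted p = 0.00969 and 0.038). After X-rays they were those of INPP5D (0.98 ± 0.15, adjusted p = 0.114), SMIM10L2B (0.97 ± 0.18) and PHLDB3 (1.33 ± 0.25). Mitotic genes had a mean of -0.55 for 4h minus 1h after X-rays (fry adjusted p = 0.376), and p53 targets a mean of 0.27 (adjusted p = 0.249). The p53 mean after C12 was 0.26 for 4h minus 1h (fry adjusted p = 0.734, and camera adjusted p = 0.005 with an estimated correlation). Without X-ray 4h replicate 2, 563 genes passed for 4h minus 1h after X-rays, and 3 passed without X-ray 1h replicate 1. With the replicate number as a random block, 4 genes passed there.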

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

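The tests of the direction, of the p53 list 1h after C12 and of a reversed dye label were chosen only after the results were seen, while both tests with further dye coefficients and the exchanges and splits of arrays were written down before their values were known.

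The deposited ratios followed neither reading of the labels in the p53 list, and of 4 sign patterns compared, features without a gene name were strongest in the dye code of the other radiation quality in 4 of 4 groups, which is what ratios turned with the wrong code would give. The p53 mean at X-ray 4h was -0.0213 ± 0.0218 (SE over genes) in the pattern of the labelled dye and 0.0419 ± 0.0282 in the untouched ratios, against 0.70 in the product, which argues against both readings if p53 targets rose after X-rays. The untouched mean at X-ray 4h lay at percentile 100 of 10000 random lists, which goes the other way, and at X-ray 1h at percentile 28.1. An additive difference between replicates 1 and 2 and replicates 3 and 4 cannot be told apart from a response by arrangement, since that pattern equals the product of both codes. The unnamed features exceeded the untouched ratios in that pattern in 1 of 4 groups. This count cannot decide, because a response would raise the same pattern. For C12 the reading leans on the rule: the p53 mean of C12 4h was 0.27 in the product and also 0.27 in the X-ray dye code, where C12 1h stood at 0.23.

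The p53 targets were lower after C12 than after X-rays at 4h (mean -0.42, fry adjusted p = 0.0232), and 1h after C12 their mean was 0.02 (fry adjusted p = 0.986). The X-ray means of this list entered the choice of direction, so the test at 4h also comes after a selection. Its call was lost on the 8 arrays alone (fry adjusted p = 0.343) and without the dye term (0.155). It was also lost without C12 4h replicate 1 (0.0644) or 3 (0.089), or without X-ray 4h replicate 3 (0.0816). At 1h the C12 arrays (-0.11 to 0.15) and the X-ray arrays (0.32 to 0.53) did not overlap (exact permutation p = 0.0286, two-sided, the smallest this design allows) and camera gave an adjusted p = 0.012 with an estimated correlation, but the list had entered the choice of direction. Scatter as a cause stays open, since fry did not pass with all arrays (adjusted p = 0.0716), without 1 array (0.0599 to 0.292), without the dye term (0.383) or with the random block (0.0648), while it passed with centring (0.0332), scaling (0.0492), the compared groups alone (0.0401) and 1 dye coefficient per quality (0.00435). Another code applied to C12 1h than to C12 4h is argued against, since all 8 pairs of a 1h and a 4h array with the same X-ray dye code correlated at 0.801 to 0.853 and all 8 with the opposite code at -0.869 to -0.803, while a wrong dye label of the C12 1h plates was not tested. A later onset after C12 stays open, because the gap between the qualities changed by -0.0160 ± 0.140 (SE over arrays) from 1h to 4h, and dose and the biological difference between the qualities were not tested here.

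Without X-ray 4h replicate 2, 1322 genes passed (187 up and 1135 down) instead of 104. A dye effect left by the shared coefficient would have lowered that count well below 1322 with 1 coefficient per quality, and 1982 passed. With 1 coefficient per group 1295 passed, so neither kind of dye effect accounts for most of the change. A reversed dye label on that array cannot be told apart here: exchanging its plates gave 2634 genes, while its p53 mean of 0.79 had the direction of the other arrays in a list that had entered the choice of direction. The culture, the RNA or the hybridisation of replicate 2 stay open as sources of its difference, and no biological explanation was tested.

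Exchanging irradiated and control plates within the arrays of 1 group allows 8 arrangements, too few for a share under 0.05. The real arrangement called 0 genes for C12 1h (8 of 8 arrangements gave as many by construction, highest other 0), 2 for C12 4h (1 of 8, highest other 0), 9 for X-ray 1h (1 of 8, highest other 0) and 104 for X-ray 4h (3 of 8, the real one included, highest other 3757). That highest arrangement follows the dye orientation, so under the reading used here it takes in a dye effect that the shared coefficient leaves. Exchanging replicate 2 alone gave 2634, which points to a structure of the X-ray 4h samples. Over all 16 arrays, 29 of 100 drawn arrangements gave as many genes as the real total of 115 (highest other 6985, median of the others 1). Arrangements that follow the dye orientation of a group can move a remaining dye effect into its mean. This share therefore cannot tell whether the total count arises by chance, and chance is neither excluded nor shown. For the 4 differences between groups, the real split gave 0 genes, so that 35 of 35 splits gave as many by construction and the count bears on nothing. The highest other split gave 0 for C12 minus X-ray at 1h, 3414 for C12 minus X-ray at 4h, 7080 for 4h minus 1h after C12 and 6238 for 4h minus 1h after X-ray. The last 3 of these splits each kept arrays of the same quality with the same dye orientation together. Under the reading used here, they take in a dye effect of each quality that 1 shared coefficient does not remove from the main model. The dye pattern had a mean square over genes of 0.1386 at C12 1h and 0.137 at C12 4h. It was 0.06238 at X-ray 1h and 0.04775 at X-ray 4h.

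Among 84 sets of 4 arrays, 4 held an array far from the others, and chance gives about 1 in 20, or 4.2. The mean of NRF2 targets was 0.51 on X-ray 4h replicate 2 against -0.21 to -0.16 on the others. That array also stood at 0.39 for double-strand break repair genes, with the others at -0.27 to -0.22. TGF-beta targets had a mean of -0.29 on X-ray 1h replicate 4, and 0.17 to 0.20 on the others. Housekeeping genes had a mean of 0.16 on X-ray 1h replicate 1 and -0.05 to -0.02 on the others. X-ray 4h replicate 2 was also high in lists that were not flagged. Housekeeping genes had a mean of 0.66 there and -0.31 to -0.06 on the others, ATF4 and unfolded protein response genes 0.62 and heat shock genes 0.59. Below 0 on that array were the histone (-0.35), leukocyte (-0.27) and fibroblast and endothelial lists (-0.28). The 13795 features without a gene name had entered the choice of direction but none of the gene tests above. Of these, 27 passed 4h after X-rays (26 up and 1 down), 1 passed 4h after C12, 1 passed 1h after X-rays and 1 passed for C12 minus X-ray at 1h.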

How the results depend on the processing

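Chosen after seeing the data were the dye coefficients per quality or per group, the other directions, and the fits with further dye coefficients that left out X-ray 4h replicate 2. Over 396 recomputed values of 36 named gene results, 0 reversed, 308 stayed on their side of the threshold, 82 lost and 6 gained a call, with 24 of the losses without a dye term and 22 with array weights. The other directions were not part of this tally, and CDKN1A at X-ray 4h stood at -0.15 as deposited and at -0.24 under the labelled dye. Changes of the dye term and robust moderation leave the estimates of a balanced dye swap as they are. For these settings 0 reversals was fixed in advance. That tally holds only the lowest and highest values of the fits without 1 array. Over all 132 such fits of the 33 called results, 49 calls were lost, and 24 of the 33 results lost theirs at least once. Robust moderation, tests per feature and a log2 threshold of 0.5 moved no count by over 1.5 times. Centring and scaling moved the median fold change by at most 0.0144. The filter on genes present on all arrays removes nothing here, signals over background were not used, and that alternative was not run. Unless stated, the cause was not tested.

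Without a dye term, 0 genes passed for C12 4h, 0 for X-ray 1h and 21 for X-ray 4h. Centring, and scaling, each left 1 for C12 4h. Array weights gave 14 for C12 4h, 2 for X-ray 4h and 3 for 4h minus 1h after C12. Fits on the compared groups alone gave 26 for C12 4h, 1 for X-ray 1h, 2 for C12 minus X-ray at 1h and 2 for 4h minus 1h after C12. For X-ray 4h they gave 83 (64 up and 19 down), of which 63 were among the 104. With the replicate block as a random term, 1 gene passed for C12 4h and 4 for 4h minus 1h after X-ray; with a fixed replicate block, 1 passed for C12 4h. The consensus correlation of that block was 0.357, and 0.0516 with 1 dye coefficient per quality, as arrays of a quality with the same number share the dye orientation. After removal of the latter, residuals of arrays with the same number at 1h and 4h correlated between -0.312 and 0.0617, and no array correlated best with its own number.

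One dye coefficient per quality gave 16 for X-ray 1h, 221 for X-ray 4h (188 up and 33 down), 6 for C12 minus X-ray at 1h and 3 for 4h minus 1h after X-ray, and all 104 genes of X-ray 4h were among the 221. One per group gave 16, 204, 6 and 3. Without X-ray 4h replicate 2, the coefficients per quality gave 1982 for X-ray 4h and 1178 for 4h minus 1h after X-ray, and those per group 1295 and 853, and 1 for C12 minus X-ray at 4h. Turned by the labelled dye alone, or as deposited, 0 genes passed for C12 4h, X-ray 1h and X-ray 4h. Turning by the code of the other quality alone puts the dye effect into the group means by construction if the likely reading holds. It gave 10157 genes for C12 1h, 10077 for C12 4h, 2441 for X-ray 1h and 1124 for X-ray 4h. It also gave 199 and 5635 for C12 minus X-ray at 1h and 4h, and 712 for 4h minus 1h after X-ray.

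Leaving out 1 array at a time gave 0 to 1 genes for C12 4h, 3 to 8 for X-ray 1h, 15 (without replicate 3) to 1322 (without replicate 2) for X-ray 4h, and 0 to 563 (without X-ray 4h replicate 2) for 4h minus 1h after X-ray, and 0 for C12 1h and the other differences. Lists past the threshold numbered 0 to 1 for C12 4h, 1 for X-ray 1h, 1 to 4 for X-ray 4h, 0 to 2 for C12 minus X-ray at 4h and 0 to 3 for 4h minus 1h after X-ray. Without replicate 1, 3 or 4 of X-ray 4h, only p53 targets passed there, and without replicate 2 mitotic (adjusted p = 0.000134), NRF2 and repair lists (0.017 each) passed with a fall. Without replicate 2, housekeeping (fry adjusted p = 0.0618) and G1/S genes (0.0659) also pointed down and did not pass. Leukocyte (0.0921) and fibroblast and endothelial markers (0.0801) pointed up. The NRF2 and repair falls therefore cannot be told apart from a broader shift of genes.

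Against 0 lists for C12 4h, 1 for X-ray 1h, 2 for X-ray 4h, 0 and 1 for C12 minus X-ray at 1h and 4h, and 0 for both time differences, camera at its preset correlation gave 3, 3, 5, 3, 4, 3 and 4. With an estimated correlation it gave 1 for C12 4h, 1 for X-ray 4h, 1 for C12 minus X-ray at 1h and 1 for 4h minus 1h after C12. Centring gave 1 for C12 4h and 1 for C12 minus X-ray at 1h, and scaling 1 for the latter. Without a dye term, 1 passed for X-ray 4h and 0 for C12 minus X-ray at 4h. On the compared groups alone, 0 passed for X-ray 1h, 1 for X-ray 4h, 1 for C12 minus X-ray at 1h and 0 for C12 minus X-ray at 4h. One dye coefficient per quality gave 1 for C12 4h, 1 for C12 minus X-ray at 1h and 1 for 4h minus 1h after X-ray. The random replicate block changed no list count.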

Other observations

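The fry test passed none of the gene groups described here with all arrays, and the values are given for X-ray 4h unless another group is named. With a preset correlation, camera passed the histone (adjusted p = 6.91e-09), G1/S (0.0205) and double-strand break repair lists (0.0205), the histone (3.26e-08) and G1/S lists (0.0415) at X-ray 1h, and the immediate early list at C12 4h (8.09e-05), and none of these with an estimated correlation. Without X-ray 4h replicate 2, fry passed the NRF2 and double-strand break repair lists (adjusted p = 0.017 each), with housekeeping genes also down but not passing (0.0618). Replication-dependent histone genes had a mean of -0.22 (37 of 42 negative, fry adjusted p = 0.588) and of -0.19 at X-ray 1h (32 of 42 negative, adjusted p = 0.949). At C12 4h the histone mean was 0.00, with 23 of 42 negative. Means were -0.09 for G1/S and replication genes, -0.09 for double-strand break repair genes, 0.07 for immediate early genes, 0.05 for NF-kB targets, 0.00 for interferon-stimulated genes, 0.01 for HIF-1 and hypoxia targets and 0.09 for ATF4 and unfolded protein response genes. They were 0.04 for heat shock genes, -0.01 for NRF2 targets, 0.03 for TGF-beta targets, -0.00 for cholesterol synthesis genes, -0.04 for ribosomal protein genes, -0.02 for ribosome biogenesis and MYC targets and 0.02 for housekeeping genes. Markers of alveolar epithelium and adenocarcinoma had a mean of 0.05, leukocyte markers of 0.03, and fibroblast and endothelial markers of 0.04. Adjusted p over these 18 lists was between 0.588 and 0.98.

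The hypoxia and immediate early genes named in advance had small estimates. At X-ray 4h, HIF1A had a change of -0.15 ± 0.25, VEGFA of 0.00 ± 0.11, the glucose transporter gene SLC2A1 of 0.46 ± 0.18, FOS of -0.16 ± 0.23, EGR1 of 0.09 ± 0.36 and ATF3 of 0.38 ± 0.14, none of which passed. At C12 4h, HIF1A stood at -0.06 ± 0.25, SLC2A1 at 0.17 ± 0.18 and ATF3 at 0.23 ± 0.14. The histone gene H1-3 had a change of -1.18 ± 0.35 at X-ray 1h (adjusted p = 1).

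The arrays of both qualities differed in scatter, in tests chosen after the values were seen. The SD among repeated features of the same accession, over 236 accessions with at least 9 features, averaged 0.0684 ± 0.00792 on C12 arrays and 0.174 ± 0.0721 on X-ray arrays (SD, n = 8 each, exact permutation p = 0.000155, two-sided). The residual SD over genes averaged 0.114 on C12 arrays and 0.283 on X-ray arrays (exact permutation p = 0.000155). On X-ray 4h replicate 2 the residual SD was 0.39, while the SD among its repeated features was 0.095. The prior SD shared by all arrays in the test was 0.2898. Of the 26 genes called in the fit on C12 4h alone, 13 were also called at X-ray 4h, against 0.147 for independent lists, and 24 had the same direction there.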
